A study of Sorghum bicolor with 12 samples.

How the data were processed

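RNA was measured in 12 libraries of middle stem internode from the sweet sorghum (Sorghum bicolor) hybrid CSH22SS, raised in an open field. Per the labels' protocols, total RNA was extracted by a modified Trizol method and libraries were made with a TruSeq Stranded Total RNA kit. The libraries fall into 6 groups of 2: booting, milky, maturity, and 3 groups labelled booting with the codes Ds1, Ds2 and Ds3. The labels do not say what Ds stands for, how severe or long a treatment was, or whether the numbers are times. The series title and the header over the Ds columns name water-limiting conditions. No label gives a batch, a harvest date or an hour of harvest.

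The authors deposited FPKM values (fragments scaled by transcript length and library size), with 1 value per group, so the authors had combined the 2 libraries of each group. The unit of all 7 columns, FPKM, comes from the name of the deposited table. The table has 2 separate parts, per the file headers. The developmental part lists 34458 loci with values for booting, milky and maturity, and the water-limiting part lists 34718 loci with values for booting again, Ds1, Ds2 and Ds3. The second booting column, handled as an other unit in the bookkeeping of columns, is likewise the authors' deposited FPKM. Locus numbers differ between the parts, and each part was scaled on its own, so ratios were taken within a part only. cutadapt 1.8.1, HISAT2 2.0.5, Bowtie2 2.2.9 and Cuffdiff are named in the submitters' processing notes, with no role, order or setting. The genome build is not given in the sources used here, and no coordinates are printed. Read totals are unknown, so no counting interval or floor is given, and an exact 0 is reported only as a value listed at 0. In the developmental part 1262 loci name several genes, whose reads cannot be separated; in the water-limiting part 819 loci share 404 gene names with another locus.

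Choices made before the data were examined assumed 1 FPKM value per library and a limma test over 12 libraries. With 1 value per group there is no spread between replicates, and no p-value, standard error or interval can be given for a gene. For that case a rule for choosing which genes to name had been fixed beforehand. Its use for counts and overlaps of loci had not, and was decided once the data were seen to hold 1 value per group. By this rule a gene locus counted as higher or lower when its ratio on FPKM + 1 was at least 4 (log2 change of 2 or more in size) and the higher group had at least 10 FPKM. These calls describe size only and have no replicate check. All log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Loci naming no gene were left out of the counts, a choice made after counts with and without them had been seen.

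The deposited table does not pair gene IDs with names, and the RefSeq gene table of assembly NCBIv3 matched 0 of its IDs. The 36 lists defined beforehand by product names could therefore not be filled. Gene names are from the sorghum literature and were recalled, not looked up in an annotation: 15 IDs were fixed before the data were examined, 44 were added afterwards but before their values were read, except GST1, whose abundance had been seen, and 3 were chosen after their values were seen. The first 2 sets, 59 IDs, form 9 lists, of which 7 had at least 3 members with a mean of at least 1 FPKM in each part. 4 IDs (1 PAL, NADP-ME, NADP-MDH and carbonic anhydrase) had no locus of their own in both parts. The values of 1 listed gene are not reported here; it remains in the median and counts of its list. For each list and comparison, the median log2 change was placed among 10000 random lists matched on mean expression in 20 bins, drawn from 14379 genes, as a description of these libraries. Random members were drawn independently of each other. Genes of 1 pathway or complex may vary together, so the percentiles of such lists can be too extreme.

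Overlaps of calls between comparisons that share booting were set beside 100 simulations of unchanged groups and beside the overlap of independent lists. Each simulation started from the mean over a part's groups and gave all comparisons the same simulated booting noise. The deposited booting values were not used, so genes high in booting alone are not represented as such. No noise estimate exists in these data, so the simulations drew noise from the maturity minus booting and the Ds3 minus Ds2 differences, which include any real effects. The booting noise came from the Ds3 minus Ds2 differences only. The scripts were tested on simulated data with a noise SD of 0.3 in log2, where genes changed 8-fold pass the size rule and those changed 2-fold fail it by construction, so this checks the code and not the rule. Alternatives were pseudocounts of 0.1 and 5, no filter (no 10 FPKM minimum for counts, no mean of 1 FPKM for lists), a mean of at least 5 FPKM, scaling by the median of ratios and quantile normalization, with others added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.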

Results

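The transcriptome of the middle stem internode of the sweet sorghum hybrid CSH22SS was recorded at booting (panicle still in the flag-leaf sheath), at the milky stage of the grain and at maturity, and in 3 further booting groups, Ds1, Ds2 and Ds3, tied by the table's header to water-limiting conditions. Each of the 6 groups had 2 libraries, combined by the authors into 1 FPKM value, so no value below has a replicate error and every difference is described by size alone. Read depth is unknown. FPKM totals were 569515 in booting, 597179 in milky and 594949 in maturity. In the separately scaled water-limiting part they were 477138 in booting, 885374 in Ds1, 682190 in Ds2 and 647608 in Ds3. The booting libraries appear in both parts, and 14379 genes could be compared: the water-limiting part read a median of 0.863 times the developmental part, the log2 ratios had an SD of 0.233 across genes, and 25 of 8642 genes at 10 FPKM or more lay at least 4-fold apart. This gap reflects the authors' processing of the same libraries and not variation between plants.

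The first question was how the internode changes from booting to the milky stage. Secondary-wall cellulose synthase (CESA) transcripts, which encode the enzymes that make the cellulose of thickened walls, were far lower in milky. CESA Sobic.001G224300 read 18.9 FPKM in booting and 0.138 in milky, Sobic.002G205500 read 25.6 and 0.249, and Sobic.003G296400 read 40.4 and 3.73, while CSLF6 (Sobic.007G050600), which makes mixed-linkage glucan, read 63.3 and 93.1. With CSLF6 included, 3 of the 4 listed synthases were at least 4-fold lower and the median log2 change was -3.63, below all 10000 matched random lists. Among 10 lignin synthesis genes, 8 were below and 2 above their booting value, none by 4-fold, with a median log2 change of -0.34 at percentile 0.96 of the random lists. PAL (Sobic.004G220300), the entry enzyme of the pathway, read 561 FPKM in booting and 236 in milky, and CCoAOMT (Sobic.010G052200) read 126 and 278. CYP79A1 (Sobic.001G012300), the first enzyme in the synthesis of the cyanogenic glucoside dhurrin, read 17.5 FPKM in booting and 0.481 in milky, the 1 member of 5 dhurrin-locus genes past 4-fold. CYP71E1 (Sobic.001G012200), the next enzyme, read 67.4 and 113, and the list's median log2 change was 0.55, at percentile 95.2.

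Between booting and milky, 0 of 8 measured genes of the sucrose enzyme list, which includes the tonoplast sugar transporter, and 0 of 3 sucrose transporters (SUT) were 4-fold apart. Sucrose synthase Sobic.010G072300 read 206 and 284 FPKM, Sobic.001G344500 read 86.2 and 157, and Sobic.001G378300 read 45.9 and 16.8. The transporter SUT1 (Sobic.001G488700) read 197 and 146 FPKM and the tonoplast sugar transporter (Sobic.004G099300) 190 and 219. The clock gene LHY (Sobic.007G047400), which peaks around dawn, read 324 FPKM in booting and 92.0 in milky, and the evening gene TOC1 (Sobic.004G216700) 18.3 and 63.4, while GI (Sobic.003G040900) read 436 and 462. The NAC gene at the stem water locus Dry (Sobic.006G147400) read 5.67 FPKM in booting and 0.0921 in milky. In all, 201 of 10244 gene loci at 10 FPKM or more were past the size rule, 80 higher and 121 lower in milky. The largest lower ratio on FPKM + 1 among loci not listed at 0 was at Sobic.009G070700, with 70.6 FPKM in booting and 0.605 in milky. With a pseudocount of 5 the count was 93.

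At maturity the cellulose synthases were again low, against the same booting libraries, and lignin genes were lower than at the milky stage. The 3 CESA genes read 0.307, 0.517 and 1.95 FPKM, in the order given above, and CSLF6 read 65.5, giving a median log2 change from booting of -3.87, below all random lists. All 10 measured lignin genes were below booting, 2 of them by at least 4-fold, with a median log2 change of -1.09, also below all random lists. CCR (Sobic.007G141200), which opens the monolignol branch, read 90.5 FPKM in booting and 10.1 in maturity, F5H (Sobic.001G196300) 45.2 and 7.50, and PAL 561 and 169. CYP79A1 read 1.41 FPKM, against a dhurrin-locus median log2 change of 0.23 at percentile 84.0. LHY, TOC1 and GI read 339, 21.0 and 438 FPKM, each within 0.19 log2 of booting. Of 9976 loci, 95 were past the size rule, 4 higher and 91 lower, and 42 were so with a pseudocount of 5.

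Maturity and milky differed at 219 loci, 76 higher and 143 lower in maturity. Lignin genes were lower in maturity at 9 of 10 members, with a median log2 change of -0.97, below all random lists. The 4 cellulose and glucan synthases had a median of -0.15, at percentile 29.9. P5CS2 (Sobic.003G356000), a proline synthesis enzyme, read 51.2 FPKM in milky and 273 in maturity. Sucrose synthase Sobic.001G378300 read 16.8 and 65.8 FPKM, whereas Sobic.001G344500 read 157 and 49.0. PPDK (Sobic.009G132900), an enzyme of C4 photosynthesis, read 80.0 FPKM in milky and 16.8 in maturity, and the C4 PEPC gene (Sobic.010G160700) stayed under 0.2 FPKM in all groups. Of the 80 loci higher in milky than booting, 69 were under 2-fold from booting in maturity and 0 were higher there by the size rule. Of the 121 lower in milky, 49 were also lower in maturity and 58 were under 2-fold from booting. Both comparisons use the same booting libraries, so part of this overlap may come from them. The count between maturity and milky was 92 with a pseudocount of 5.

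**Figure D1:**
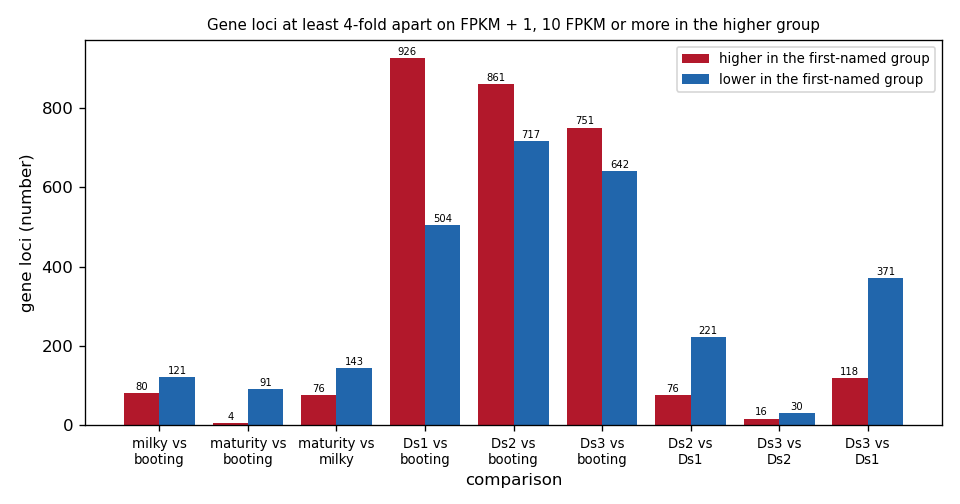
Number of gene loci at least 4-fold apart on FPKM + 1 with 10 FPKM or more in the higher group, for each comparison on the horizontal axis; red bars are loci higher and blue bars loci lower in the first-named group. Each group is 1 combined value of 2 libraries, so there are no error bars; Ds1, Ds2 and Ds3 against booting give 1430, 1578 and 1393 loci, and the stage comparisons 95 to 219.

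The second question was how the booting internode differs under the conditions labelled Ds1, Ds2 and Ds3. In Ds1, lignin and cellulose synthase genes were lower, and a proline synthesis gene and a sucrose synthase higher. Of 10 lignin genes all were below booting, 4 by at least 4-fold, with a median log2 change of -1.45 at percentile 0.01. CCR read 78.3 FPKM in booting and 4.45 in Ds1, F5H 36.0 and 0.875, and C3H (Sobic.009G181800) 32.9 and 3.09. The 3 CESA genes, read at 16.9, 22.2 and 34.9 FPKM in booting, were at 1.83, 1.58 and 1.01, and CSLF6 at 54.7 and 13.6, for a median of -2.91, below all random lists. The 3 CESA genes, though not CSLF6, were also low in milky and maturity. Their low values are therefore not particular to the Ds groups. All these list results are set against the same booting libraries and are not independent. P5CS2 read 123 and 1224 FPKM, sucrose synthase Sobic.010G072300 read 178 and 1098, and the Dry gene 4.89 and 33.2. Among 5 measured flowering and height genes the median was 2.63-fold higher, at percentile 99.0, with 4 members above booting and 1 below. The same list was at percentile 77.5 in Ds2 and 86.1 in Ds3, inside the central 95%. The phytochrome genes PHYB (Sobic.001G394400) and PHYC (Sobic.001G087100) read 8.29 and 20.1 FPKM in booting and 21.3 and 54.4 in Ds1, and the auxin transporter Dw3 (Sobic.007G163800) 4.87 and 27.2. LHY read 285 and 40.1 FPKM, TOC1 15.9 and 57.7, and GI 352 and 178. The dehydrin DHN1 (Sobic.009G116700), a protein family of dehydrating tissue, named after its values were seen, read 0.664 FPKM in booting and 1197 in Ds1. Of 5 dhurrin-locus genes 4 were below booting, with a median of -0.46 at percentile 18.3: CYP79A1 read 15.1 and 1.16 FPKM, CYP71E1 58.2 and 25.5, and GST1 (Sobic.001G012500) rose from 2266 to 6112, a log2 change of 1.43 whose sign turned to -0.37 under quantile normalization.

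Ds1 differed from booting at 1430 of 10320 loci, 926 higher and 504 lower. In Ds1 the top 10 loci held 29.9% of all FPKM and loci naming no gene 9.41%, against 6.51% and 1.75% in booting. The highest was Sobic.004G337132, with 97.0 FPKM in booting and 65970 in Ds1. The median log2 change of expressed loci was -0.05. The count was 806 with a pseudocount of 5.

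In Ds2 most wall genes were again below booting and dhurrin genes were lower than in Ds1. Of the listed sucrose-phosphate synthases, 1 that was low in booting was far higher than there, as was a cell-wall invertase. Against Ds1 all 5 dhurrin-locus genes were lower, 1 of them by at least 4-fold. Their median log2 change was -0.76 at percentile 1.155, or 2.84 among genes with a mean of at least 5 FPKM. Of 10 lignin genes 9 were below booting, 7 of them at least 4-fold, and HCT (Sobic.004G212300) was not, with a median log2 change of -2.26, below all random lists. HCT read 30.7 FPKM in booting and 32.6 in Ds2. The same booting libraries read 63.15 for HCT in the developmental part, so its direction is uncertain. PAL read 486 FPKM in booting and 48.6 in Ds2. The 4 glucan and cellulose synthases had a median of -3.47, also below all random lists. The dhurrin locus had a median of -1.60 at percentile 0.805, or 2.70 among genes with a mean of at least 5 FPKM, with CYP79A1 at 15.1 and 0.0112 FPKM, UGT85B1 (Sobic.001G012400) at a log2 change of -2.87, and CYP71E1 at 58.2 and 18.6. GST1 read 3605 FPKM, a log2 change of 0.67 that turned to -1.21 under quantile normalization. Sucrose-phosphate synthase Sobic.005G089600 read 0.953 FPKM in booting and 23.3 in Ds2, and the cell-wall invertase Sobic.004G166700, named after its values were seen, 5.09 and 45.2. The other listed sucrose-phosphate synthases moved less. Sobic.009G233200 read 59.0 and 45.8 FPKM, Sobic.004G068400 30.35 and 27.9, Sobic.003G403300 14.05 and 21.0, and Sobic.010G205100 8.87 and 16.6. The tonoplast sugar transporter read 164 FPKM in booting and 80.3 in Ds2. Sucrose synthase Sobic.001G344500 read 74.5 and 15.5 FPKM, but the other listed sucrose synthases were above booting. Sobic.010G072300 read 178 and 447 FPKM, Sobic.001G378300 39.4 and 81.5, and Sobic.004G357600 0.378 and 2.49. The 8 genes of the sucrose enzyme list expressed in both parts, which leave out Sobic.005G089600, had a median log2 change of 0.22 at percentile 68.2. With those expressed in the water-limiting part, a filter tried after the list results were seen, it was 0.83 at percentile 97.6. The genes this added, Sobic.005G089600, Sobic.004G357600 and the vacuolar invertase Sobic.004G004800, read under 1 FPKM in booting. They passed the filter only through their Ds values, so the higher percentile is no support for a rise. DHN1 read 2284 FPKM and P5CS2 406. LHY read 20.7 FPKM, TOC1 92.8 and GI 185. Of 10336 loci, 1578 were past the size rule, 861 higher and 717 lower. The top 10 loci held 22.8% of FPKM and loci naming no gene 7.40%. With a pseudocount of 5 the count was 839, and at a ratio of 2 lower loci outnumbered higher ones, 2239 to 1854.

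In Ds3 the lignin list reached a median log2 change of -2.81 and the cellulose and glucan synthases -3.93, both below all random lists. CCR read 1.45 FPKM and PAL 18.5, whereas C4H (Sobic.002G126600) read 61.7 in booting and 80.5 in Ds3. The dhurrin locus had a median of -2.89 at percentile 0.01, with CYP71E1 at 6.98 FPKM and the transporter MATE2 (Sobic.001G012600) at 82.7 in booting and 26.3 in Ds3. GST1 read 3157 FPKM, a log2 change of 0.48 that turned to -1.03 under quantile normalization. The cell-wall invertase read 131 FPKM and sucrose-phosphate synthase Sobic.005G089600 25.1. The vacuolar invertase Sobic.004G004800 read 0.277 and 4.19 FPKM, and sucrose synthase Sobic.001G344500 fell from 74.5 to 19.7. The other listed sucrose synthases, Sobic.010G072300, Sobic.001G378300 and Sobic.004G357600, read 364, 104 and 2.34 FPKM, each above booting. The sucrose enzyme list had a median of 0.53 at percentile 88.8, or 97.54 with no filter. SUT1 read 170 FPKM in booting and 92.4 in Ds3, SUT2 (Sobic.004G353600) 19.2 and 17.8, and SUT4 (Sobic.008G193300) 40.9 and 62.5, but SUT2 and SUT4 read 30.4 and 71.3 for the same booting libraries in the developmental part. The Dry gene read 3.57 FPKM, Dw3 6.24 and P5CS2 303. LHY, TOC1 and GI read 45.8, 67.0 and 253 FPKM. Of 10276 loci, 1393 were past the size rule, 751 higher and 642 lower. The largest lower ratio on FPKM + 1 among loci not listed at 0 was at Sobic.002G322000, with 651 FPKM in booting and 1.02 in Ds3. The top 10 loci held 20.6% of FPKM and loci naming no gene 6.71%. With a pseudocount of 5 the count was 773, and at a ratio of 2 lower loci outnumbered higher ones, 2044 to 1787.

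**Figure D2:**
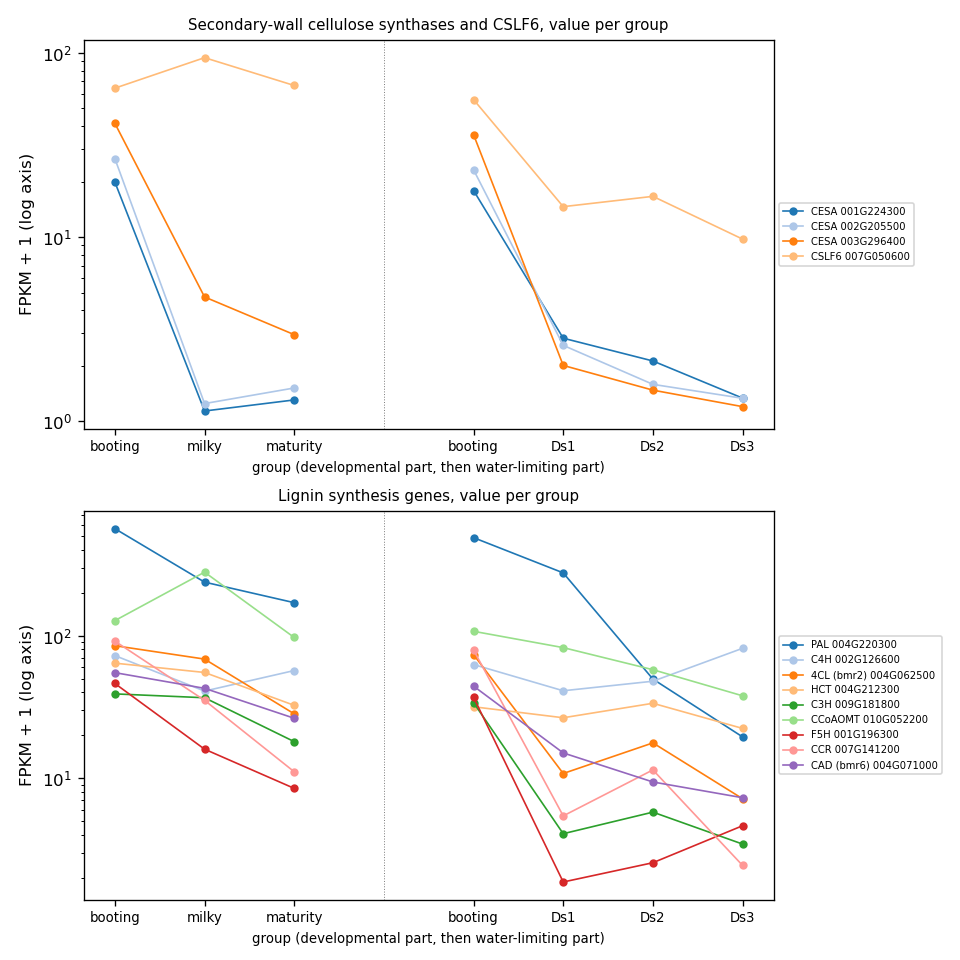
FPKM + 1 on a log axis for cellulose and mixed-linkage glucan synthase genes (upper) and 9 lignin synthesis genes (lower) in each group, with the developmental part left of the dotted line and the water-limiting part right of it. Each point is 1 combined value of 2 libraries, the joining lines only guide the eye and Ds1 to Ds3 are in label order; CESA Sobic.001G224300 reads 18.9 FPKM in booting and 0.138 in milky.

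Among the Ds groups, Ds2 and Ds3 were closest. Ds3 and Ds2 differed at 46 loci, 16 higher and 30 lower in Ds3, and Ds2 and Ds1 at 297, 76 higher and 221 lower in Ds2. Ds3 and Ds1, a comparison added after seeing the data, differed at 489, 118 higher and 371 lower in Ds3. With a pseudocount of 5 these counts were 14, 137 and 245. Between Ds1 and Ds2, PAL read 274 and 48.6 FPKM, UGT85B1 11.4 and 1.33, and the cell-wall invertase 5.62 and 45.2. The lignin list had 6 of 10 members above their Ds1 value in Ds2, with a median log2 change of 0.28 at percentile 98.7, or 96.3 with a pseudocount of 5, although its median against booting was lower in Ds2 than in Ds1. Between Ds2 and Ds3, CCR read 10.5 and 1.45 FPKM and Dw3 27.6 and 6.24, and 8 of 10 lignin genes were lower in Ds3, with a median of -0.60 below all random lists. Of 926 loci higher in Ds1 than booting, 478 were also higher in Ds2 and Ds3, and 152 were under 2-fold from booting in Ds3. Of 504 lower in Ds1, 329 were lower in all 3 Ds groups.

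The comparisons against booting share its libraries. Among genes with a locus of their own in both parts, 424 were higher and 290 lower in both Ds1 and Ds3, where independent lists would share 35.3 and 28.1 and simulated unchanged groups shared a mean of 9.37 in all. Milky and Ds2 shared 10 higher and 56 lower genes, against 0.473 and 6.93 for independent lists and a mean of 9 in the simulations. Milky and maturity shared 0 higher and 43 lower genes, against 0.977 lower for independent lists and a mean of 9.7 in all in the simulations. Genes called in opposite directions numbered 6 for Ds1 and Ds3, 13 for milky and Ds2 and 1 for milky and maturity. For milky and Ds2 this was more than the 10 shared higher, so their overlap is not one of direction alone. Part of each excess of shared genes may come from the shared booting libraries, which cannot be split. The covariance of log2 changes across genes was 1.25 for Ds1 and Ds3, against 0.103 simulated, and 0.0707 for milky and Ds2, against 0.103 simulated. For milky and maturity it was 0.0835, against 0.109 simulated. Genes are not independent replicates. In a comparison that shares no library, milky minus maturity against Ds2 minus booting, the correlation across 14379 genes was 0.02. Changes that milky and maturity have in common cancel there, such as those of the 49 of 121 loci lower in both. It therefore cannot decide whether the genes lower in both milky and Ds2 come from the shared booting libraries.

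**Figure D3:**
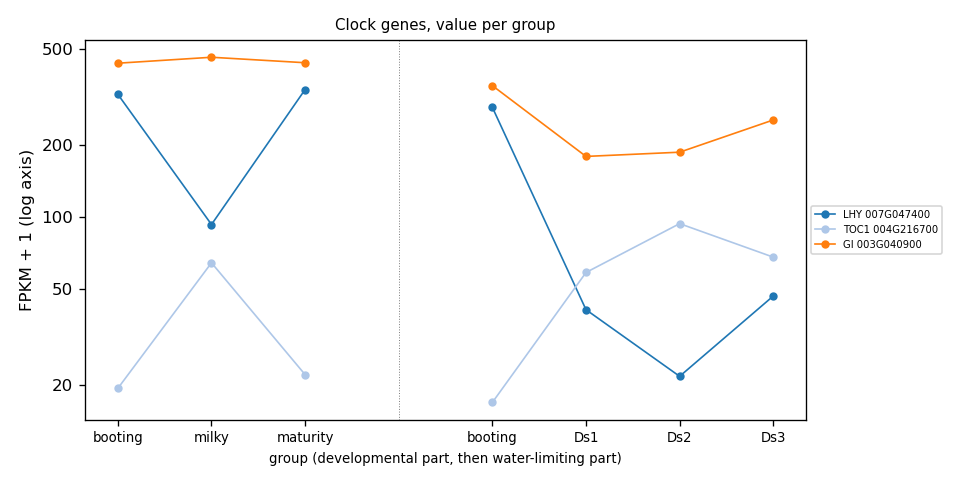
FPKM + 1 on a log axis for the clock genes LHY, TOC1 and GI in each group, with the developmental part left of the dotted line. Each point is 1 combined value of 2 libraries and the lines only guide the eye; LHY reads 324, 92.0 and 339 FPKM in booting, milky and maturity, and 285, 40.1, 20.7 and 45.8 in booting, Ds1, Ds2 and Ds3.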

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

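The tests of this part were chosen after the results were seen, and no difference between genes or groups here was tested against replicate error. Of the named genes reported, 4 lay on opposite sides of booting in milky and in maturity by a log2 change of at least 0.5 in each, with 10 FPKM or more in at least 1 of the stages; other named genes did so with less than 0.5 on at least 1 side. The differences of log2 change, maturity minus milky, were -1.66 for sucrose synthase Sobic.001G344500, 1.90 for sucrose synthase Sobic.001G378300, -2.18 for PPDK and 2.39 for P5CS2, and whether they differ beyond replicate error was not tested. Loci naming no gene, which the counts leave out, held 9.41% of FPKM in Ds1, 7.40% in Ds2 and 6.71% in Ds3, above the 1.75% in booting; a share of FPKM is not a share of reads.

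Ds1, Ds2 and Ds3 differed from booting at many more loci than milky or maturity did. If a few very abundant loci had compressed the values of all others by a common factor, some factor applied to a Ds group would bring its count down to the 201 of milky. The lowest count under any factor was 1401 in Ds1, 1572 in Ds2 and 1388 in Ds3, so no common factor accounts for the counts. That outcome was foreseeable, because the authors' scaling left median log2 changes of only -0.05, -0.08 and -0.05. It therefore says nothing on other effects of the abundant loci. Noise from fewer reads per locus is not covered because depth is unknown. A separate batch of Ds libraries stays open, since no label gives a batch and the 9.41% in Ds1 can come from a batch or from the condition, so batch and group cannot be told apart. The biological difference named by the design, water limitation, is also open and was not tested.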

How the results depend on the processing

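No paired analysis was possible because the table holds 1 value per group and its columns carry no replicate number. For the same reason the limma fits, moderated F tests over stages and over Ds groups, other eBayes settings, fits on fewer groups, replicate weights, camera and fry, leaving out a replicate and the alternative without a minimum change were not run, and depth is unknown. The planned filter on libraries had no counterpart, so "no filter" means no 10 FPKM minimum for counts of loci and no mean of 1 FPKM for gene lists. Added after seeing the data were ratios of 2 and 8, loci naming no gene, loci listed at 0, genes whose booting values lay within 1.2-fold, runs of neighbours, a filter per part of the table for lists, quantile normalization for named genes and Ds3 minus Ds1. Comparisons are given in the order milky, maturity, Ds1, Ds2 and Ds3 against booting, then maturity minus milky, Ds2 minus Ds1, Ds3 minus Ds2 and Ds3 minus Ds1. A pseudocount of 5, which shrinks ratios of low genes by construction, gave 93, 42, 806, 839, 773, 92, 137, 14 and 245 loci. A ratio of 2 gave 987, 348, 3959, 4093, 3831, 1341, 1093, 381 and 1803, and a ratio of 8 gave 85, 51, 702, 781, 691, 78, 103, 13 and 171. Genes shared by Ds1 and Ds3 numbered 393 with a pseudocount of 5, against 714; by milky and Ds2, 31, and 100 with no filter, against 66, the cause of which was not tested; by milky and maturity, 21, against 43. Other counts stayed within 1.5 times. Neither the median of ratios nor quantile normalization moved the share of higher calls by over 10 percentage points. Other settings did: a ratio of 2 for maturity against booting (4.21% to 15.2%), maturity minus milky (34.7% to 46.7%), Ds1 (64.8% to 51.0%) and Ds3 minus Ds1 (24.1% to 35.8%), a ratio of 8 for Ds1 (to 74.8%), Ds2 (54.6% to 65.2%) and Ds3 minus Ds2 (34.8% to 46.2%), and a pseudocount of 5 for Ds2 (to 65.9%). At a ratio of 2 the majority turned in Ds2 (1854 higher, 2239 lower) and Ds3 (1787 and 2044). The number of list medians outside the central 95% was 23 of 63 and 19 to 24 of the same 63 under the alternatives. With no filter 1 more list entered, giving 25 of 72. The 3.15 given by chance holds only for independent pairs, whereas these comparisons share groups. Most of the 23 came from the lignin list and the cellulose and glucan synthase list. Sucrose enzymes in Ds2 moved from percentile 68.2 to 97.6 when genes had to be expressed in the water-limiting part only, a filter tried after the list results were seen. That filter added genes low in booting that passed through their Ds values. In milky the sucrose enzymes were at percentile 0.84 with no filter. The dhurrin locus in Ds2 moved from percentile 0.805 to 2.70 with a mean of at least 5 FPKM.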

Other observations

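Of the tests below, only the count of neighbouring pairs was set before its result was seen; the others were chosen after. Genes of flowering and stem height not described above include the kinase gene Dw2 (Sobic.006G067700), which read 14.4 FPKM in booting and 50.4, 59.0 and 40.3 in Ds1, Ds2 and Ds3, and Dw1 (Sobic.009G229800), which read 12.2 in booting and 5.13, 5.36 and 6.28. The florigen-family gene CN15 (Sobic.010G045100), named after its values were seen, was listed at 0 in booting and at 53.1, 11.8 and 6.35 FPKM in Ds1, Ds2 and Ds3, so no fold is given. The small subunit of Rubisco (Sobic.005G042000) read 29.5 FPKM in booting and 96.0, 95.3 and 51.1 in the Ds groups, while PPDK read 37.0 in booting and 15.0, 19.4 and 9.85.

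LHY was lower and TOC1 higher in milky than in booting and maturity, and the same held in the Ds groups against booting. Another hour of harvest may give this. A shift that raises TOC1 was assumed to raise GI too, which was not tested. The LHY log2 change of -1.80 in milky came with a GI change of 0.08. Against booting, GI changed by -0.98 in Ds1, -0.92 in Ds2 and -0.47 in Ds3. As the assumption may not hold, these values do not decide it. For 1 harvest-time difference behind both milky and Ds, an assumed bound was set. Over 60% of the genes 4-fold apart between milky and maturity and at least 2-fold from booting in Ds were taken to go the same way. The bound was not derived from clock genes. The rule was changed after the values were seen, to need all 3 Ds groups below it. In Ds3 60 of 120 did (50%, exact 95% interval 40.7 to 59.3), in Ds1 61 of 120 (50.8%, 41.5 to 60.1) and in Ds2 68 of 130 (52.3%, 43.4 to 61.1), which leaves it open in all 3, since the intervals treat genes as independent and are too narrow. The labels give no hour, so harvest time cannot be told apart from stage or water limitation, which stay open and untested.

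Genes changed alike lay next to each other in ID order in the Ds groups, with 170 adjacent pairs in Ds1, 188 in Ds2 and 148 in Ds3, against 94.8, 110.4 and 86.5 in permuted orders (permutation p = 0.000999 each, the smallest that 1000 permutations can give). In milky there were 5 pairs against 1.90 (permutation p = 0.041). The longest run was 15 genes beginning at Sobic.003G171900, and with 7 genes of a nearby run it makes 22 genes with a median of 4.99 FPKM in booting and 124, 150 and 162 in Ds1, Ds2 and Ds3. A candidate explanation is 1 common source of reads for the block. The SD of its log2 ratios in Ds1, 1.36, lay at percentile 6.45 of random sets of other genes higher in all Ds groups. Among sets of such genes with booting values in the block's range it lay at percentile 13.2. Neither decides it. In milky 15 of the 15 block genes that could be followed were below booting, values seen before any test, and in maturity 14 were. The median ratios to booting were 0.523 in milky and 0.412 in maturity. Genes regulated together would do the same, and a genome was not used here.

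In the water-limiting part 22 loci, and in the developmental part 4, were listed at 0 in 1 group and at 50 FPKM or more in another. With the 22 sorted by locus number, 4 adjacent pairs lay 2 or fewer numbers apart, against a mean of 0.0458 in random draws (permutation p = 1.0e-04, the smallest that 10000 draws can give).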
